A study of Homo sapiens with 24 samples.

How the data were processed

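Gene expression was measured by RNA sequencing of frozen liver tissue from 24 people, 1 library each. Per the labels, 16 libraries belong to a group called IND-PALF, 6 to a group called DX-PALF, and 2 to normal controls (CONTROL), and the first 2 groups are children in acute liver failure. The labels expand neither abbreviation, so both are used as given; the title of the series speaks of indeterminate pediatric acute liver failure. Replicate numbers follow the order of the records and pair no samples. The deposited files, 1 per library, hold raw counts of reads per gene as whole numbers under Ensembl gene IDs, with no normalization. Per the submitters' processing notes, the authors trimmed reads with cutadapt 1.13, aligned them with STAR, counted them with HTSeq 0.6.1p1 and tested them with DESeq2. The notes name the genome builds mm10 and hg19 without saying what each was used for, and they do not say whether the counting used strand. The files list human gene IDs.

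Of 35700 gene IDs, 24635 were matched to a name in GENCODE v29, which was used for names only. The other 11065 IDs had no name, and 2502 of them had reads. Unnamed IDs stayed in the library sizes and in the tests and are not discussed one by one. XIST, TSIX and the Y-linked genes, 102 in all, were left out of every table because the samples come from human donors. None of the 276 pairs of libraries held identical counts. All 13 mitochondrial mRNAs were listed at 0 in every library, as were CCL5, PECAM1, CD24 and LIN28B, so nothing is said about these genes.

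Total counts ran from 587080 to 14605112 per library, and between 11074 and 20291 genes per library had at least 1 read. In 8 libraries the 2 largest unnamed IDs (ENSG00000226958 and ENSG00000239776) held over 30% of all counts. These 8, called high-share libraries here, are IND-PALF replicates 9 to 14 and DX-PALF replicates 1 and 2. The other 16, called low-share libraries, are both controls, 10 of IND-PALF and 4 of DX-PALF. The split was made from the counts and is not a grouping of the study. By the numbers in the sample titles, however, the 8 high-share libraries form an unbroken run. The low-share libraries numbered before this run are all IND-PALF. Those numbered after it are both controls, the 4 of DX-PALF and only 2 of the 10 of IND-PALF. In the low-share set the group is therefore largely tied to the run of titles. Results are given within the split where they differ.

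Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided, TMM normalization). One model held the means of the 3 groups, so that the groups shared 1 estimate of the spread, because 2 controls alone leave too few degrees of freedom. Genes with low counts were removed with filterByExpr (minimum count 10), which left 15542 genes. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.468. The p-values of single genes and of list scores measure the spread between these samples. Camera, the list test described below, sets a list's genes against the other genes. With its preset correlation it takes little account of list genes that move together between libraries. In nearly all random splits of the IND-PALF and DX-PALF libraries, described below, camera called lists too. A camera call alone therefore does not show a difference between groups. Every adjusted p given for a gene comes from edgeR and every adjusted p given for a gene list from limma 3.58.1, unless another test is named. Expression is given as CPM (counts scaled to a TMM-adjusted library size of 1e+06), as mean ± SD over the libraries of a group, and fold changes are fitted log2 values with their standard errors (SE).

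Gene lists were tested with camera from limma (correlation preset at 0.01, log2 CPM with a prior count of 2), two-sided, and adjusted over the lists of a comparison. Camera with the correlation estimated from the data and fry were run beside it. Of 29 disjoint lists (365 genes), 28 could be tested and the list of mitochondrial mRNAs could not. The number of a list's genes that passed is given over all genes tested and adjusted over the list alone. A list score per library is the mean log2 CPM of its genes, and scores of 2 groups were compared by a two-sided exact permutation test over all splits, adjusted over the 28 lists. With 16 against 2 libraries no p under 0.00654 can occur, and with 6 against 2 none under 0.0357. Relations between scores across libraries used permutation tests with 100000 resamples, and were given only where the largest gap between neighbouring values of the CD8 score was at most 0.4 of its range. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for scores and figures.

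The groups, comparisons, tests, lists and the rule for naming genes were chosen before the data were examined. For each comparison, the rule names the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 2. It leaves out clone and locus names, immunoglobulin and T cell receptor segments and the sex-linked genes. It adds the first gene of each list and each list's called gene with the smallest p per direction, and a gene named in 1 comparison may be quoted in the others. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. A floor is 3 counts over the libraries of a group, and intervals are at 95% confidence.

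The steps were tested on counts simulated from the libraries' own means and sizes, with 200 genes changed. For IND-PALF against CONTROL (15308 genes), 9% of 100 genes changed by 1 on the log2 scale and 53% of 100 changed by 2 were recovered, with 5 false calls. For DX-PALF against CONTROL (15450 genes), 4% and 41% were recovered with 0 false calls. For IND-PALF against DX-PALF (15372 genes), 38% and 84% were recovered with 7 false calls. A list changed in the simulated IND-PALF libraries was found by camera, by camera with an estimated correlation and by fry in both comparisons that involve IND-PALF. Of 28 unchanged lists, camera called 2 for IND-PALF against CONTROL and 0 in the other comparisons, and the other 2 tests called 0. The simulated genes were drawn independently of each other, whereas genes of a real list can move together. These list results therefore do not show how often unchanged lists are called in the real libraries.

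The alternatives tried were DESeq2 size factors (RLE) for normalization, no filter on low counts, a fit of only the 2 groups compared, the total count as a covariate, a fit without the 7 libraries with the lowest totals (IND-PALF replicates 9 to 14 and DX-PALF replicate 2), limma voom with quality weights, the DESeq2 1.42.0 Wald test, and each CONTROL or DX-PALF library left out in turn. For scores they were a prior count of 0.5 and the median of members. Alternatives added after seeing the counts were the low-share libraries alone, the high-share libraries alone, the share as a batch term, and removal of the 2 unnamed IDs. Reads of near-identical copies (CYP2A6, CYP2A7 and CYP2B6, CYP3A4 and CYP3A7, HSPA1A and HSPA1B, SAA1 and SAA2, ORM1 and ORM2) can be split between them by the counting, so single values of these genes are uncertain. Genes that overlap an antisense partner are uncertain too, since the use of strand is not stated.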

Results

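Liver RNA was sequenced from 22 children in acute liver failure, 16 in the group IND-PALF and 6 in the group DX-PALF, and from 2 normal controls. Total counts per library ran from 610270 to 13579294 in IND-PALF, from 587080 to 14605112 in DX-PALF, and were 11769926 and 8118837 in the 2 controls. In 8 libraries of low depth (587080 to 1881478 counts), 41.6% to 71.5% of all counts fell in 2 unnamed gene IDs. These high-share libraries are 6 of IND-PALF and 2 of DX-PALF. In the 16 low-share libraries, which include both controls, the same 2 IDs held 0.32% to 24.8% of counts.

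**Figure D1:**
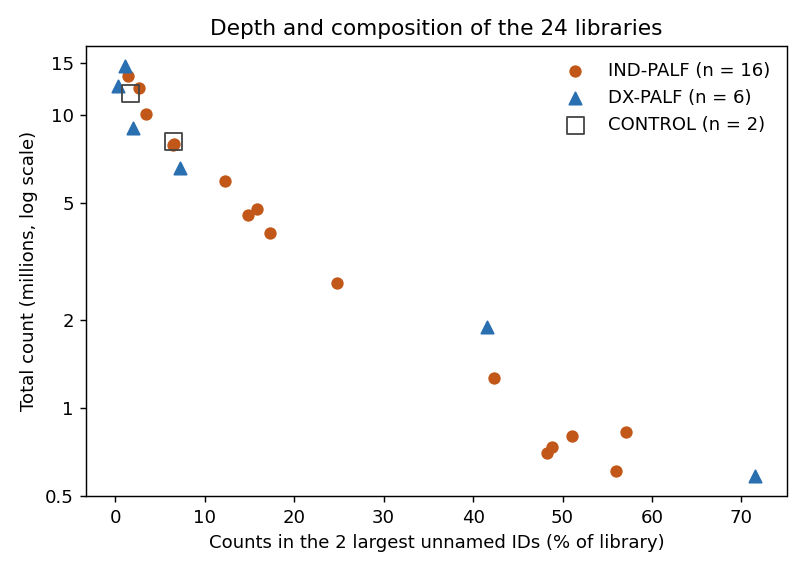
Total count per library (y axis, in units of 1e+06 counts, log scale) against the percent of its counts in the 2 largest unnamed gene IDs (x axis), with IND-PALF as orange circles, DX-PALF as blue triangles and CONTROL as open black squares. The 8 libraries above 41% lie at or below 1881478 counts, and the other 16 lie between 2656792 and 14605112.

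The first comparison asked how liver tissue of the IND-PALF group differed from normal liver. By camera, genes of cell division were higher in IND-PALF and genes of acute phase proteins, which the liver secretes during inflammation, were lower. Neither list passed with an estimated correlation (camera adjusted p = 0.092 for each). MKI67 (ENSG00000148773), a marker of dividing cells, averaged 147.5 ± 85.2 CPM in IND-PALF (SD, n = 16) against 9.63 ± 2.99 CPM in the controls (n = 2), a log2 fold change of 3.92 (SE 0.93, edgeR adjusted p = 0.0156). CRP (ENSG00000132693), an acute phase protein, averaged 90.9 ± 83.2 CPM against 3629 ± 3146 CPM, a log2 fold change of −5.31 (SE 0.83, adjusted p = 0.000384), and was below both controls in 16 of 16 libraries. With edgeR, 247 genes rose and 414 fell among 15542 genes tested, 243 and 372 of them by at least 2-fold, and 2987 genes had an unadjusted p under 0.05. With either control left out, far fewer genes were called. Most of these calls were lost, and nearly all of those of higher genes. Only 1 control is left then, so the drop can come from the smaller group as well as from the control removed. Among the low-share libraries alone, 523 genes rose and 570 fell, including 605 of the 660 calls that could be tested there.

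Of 15 cell cycle genes, 11 rose in IND-PALF against CONTROL, and 15 did so adjusted over the list alone. The list had a median log2 fold change of 3.43 (camera adjusted p = 8.49e-21, adjusted p = 0.092 with an estimated correlation), and 3.27 in the low-share libraries. CDK1 (ENSG00000170312), the kinase that drives entry into mitosis, averaged 16.1 ± 6.19 CPM against 1.1 ± 0.08 CPM, a log2 fold change of 3.86 (SE 0.66, adjusted p = 0.000992), and lay above both controls in 16 of 16 libraries. Other genes of DNA replication and mitosis rose too: ASPM by 4.36 on the log2 scale, CCNA2 by 4.30, MYBL2 by 4.4, EXO1 by 5.05 and PBK by 5.21, with adjusted p between 0.00461 and 0.0184. CDK1 kept its call when either control was left out (adjusted p 0.036 without CONTROL replicate 1 and 0.0342 without replicate 2). MKI67 lost it without replicate 1 (log2 fold change 4.27, adjusted p 0.142) and without replicate 2 (3.63, 0.178). ASPM (5.19 and 3.85), MYBL2 (4.60 and 4.24) and PBK lost theirs without either control, and CCNA2 (3.72) and EXO1 (4.23) without replicate 2.

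Acute phase proteins had a median log2 fold change of −3.09 in IND-PALF against CONTROL (camera adjusted p = 3.12e-14, adjusted p = 0.092 with an estimated correlation), and −2.95 in the low-share libraries. Of 13 genes, 7 fell (CRP, LCN2, ORM1, ORM2, SAA1, SAA2 and SERPINA3), and 11 did so adjusted over the list alone. SAA1 (ENSG00000173432) and SAA2 (ENSG00000134339), near-identical copies that encode serum amyloid A, averaged 23.4 ± 27.1 and 9.19 ± 11.2 CPM (n = 16) against 1591 ± 590 and 1122 ± 584 CPM (n = 2). Their log2 fold changes were −6.10 (SE 0.92, adjusted p = 0.000293) and −6.84 (SE 0.87, adjusted p = 3.07e-05), and both kept their calls in every alternative run. CRP had −3.94 without CONTROL replicate 2 and was then not called (adjusted p 0.0786).

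In other large falls the 2 controls differed from each other, and some of the calls hung on 1 of them. FGF23, a hormone of phosphate balance, fell by 5.72 (SE 0.71, adjusted p = 2.64e-05), with 32.6 and 99.9 CPM in CONTROL replicates 1 and 2, and kept its call in every alternative run. MYH4, a myosin of fast skeletal muscle, fell by 7.99 (SE 1.07, adjusted p = 5.87e-05), with 99.2 and 23.6 CPM, and lost its call with DESeq2 (adjusted p 0.16). C2CD4A fell by 5.68 (adjusted p = 7.22e-07), with 9.57 and 145 CPM, and CHI3L1, a secreted glycoprotein of inflamed and remodelling tissue, fell by 6.01 (adjusted p = 7.12e-05), with 10.7 and 599 CPM. Without CONTROL replicate 2 these 2 had log2 fold changes of −2.69 and −1.17 and were not called (adjusted p 0.0786 and 0.728). The cytokine genes IL1B and IL6 and the protease gene MMP9 fell by 3.06, 3.97 and 3.26, and were at 1.08, −0.78 and −0.33 without CONTROL replicate 2, none of them called. SDC1, a surface proteoglycan of plasma cells and of hepatocytes, fell by 2.23 (adjusted p = 0.0242), and lost its call without CONTROL replicate 1 (−1.58, adjusted p 0.455) and without replicate 2 (−2.67, 0.0762).

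All 7 lists of hepatocyte function were lower in IND-PALF than in CONTROL by camera. Median log2 fold changes were −1.93 for hepatocyte secreted proteins (adjusted p = 5.08e-07), −1.94 for coagulation factors (7.13e-07), −1.72 for the urea cycle (0.00046), −1.57 for bile acid synthesis and transport (6.78e-06), −1.91 for cytochrome P450 drug metabolism (2.41e-06), −0.95 for fatty acid oxidation and ketogenesis (0.000915) and −1.30 for gluconeogenesis and glycogen (0.000686). None of these lists passed with an estimated correlation, adjusted p from 0.34 to 0.524. Within the low-share libraries the medians ran from −2.25 (cytochrome P450) to −1.29 (fatty acid oxidation), all called. Single genes passed less often: CYP2A6, CYP2B6 and CYP3A4 among the P450 genes, CYP7B1 (−1.37, adjusted p = 0.0491) of bile acid synthesis and NAGS (−2.96, adjusted p = 0.00873), which makes the activator of the first urea cycle enzyme. Adjusted over the list alone, 6 P450 genes, 3 bile acid genes, 2 gluconeogenesis genes, 1 urea cycle gene, 1 secreted protein gene, 0 coagulation genes and 0 fatty acid genes passed. ALB (albumin) averaged 17470 ± 20770 CPM in IND-PALF and 39720 ± 28240 CPM in CONTROL and was not called (log2 fold change −1.19, adjusted p = 0.688).

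CONTROL replicate 1 decided the P450 genes. CYP3A4 and CYP2B6, enzymes that break down drugs, were at 1090 and 1470 CPM in CONTROL replicate 1 and at 10.4 and 17.9 CPM in replicate 2. CYP3A4 had a log2 fold change of −5.41 (SE 1.29, adjusted p = 0.0156) with both controls and 0.27 (adjusted p 0.987) without replicate 1. CYP2B6 went from −5.78 to −0.48, its relative CYP2A7 from −6.93 to −2.75 and NAGS from −2.96 to −0.73, and all 3 lost their calls. CYP7B1 lost its call without replicate 1 (−1.27, adjusted p 0.343), without replicate 2 (−1.46, 0.188) and without DX-PALF replicates 3, 4 or 6 (0.0526 to 0.0608). Without replicate 1 the lists of P450 (−0.10), urea cycle (−0.82), fatty acid oxidation (−0.19) and gluconeogenesis (−0.46) were not called, while secreted proteins (−1.27), coagulation factors (−1.72) and bile acid synthesis (−0.65) were. All 7 stayed called without CONTROL replicate 2, with medians from −2.79 (P450) to −1.58 (fatty acid oxidation).

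Immune lists were higher in IND-PALF than in CONTROL by camera, with few single genes passing. Median log2 fold changes were 1.66 for T cell markers (adjusted p = 5.54e-08), 2.22 for CD8 and cytotoxic effector genes (7.13e-07), 1.48 for resident memory T cell genes (0.00235), 1.98 for immune checkpoint genes (0.000237), 2.18 for NK cell markers (0.00216), 3.09 for B cell markers (0.000915), 1.69 for the interferon gamma response and its chemokines (4.03e-12) and 1.43 for Kupffer cell markers (0.000237). With an estimated correlation none passed (adjusted p 0.34 or 0.341). Their medians within the low-share libraries were between 1.41 and 3.26, all called. The called genes were CIITA (log2 fold change 2.84, SE 0.79, adjusted p = 0.0403), CXCL10 (5.10, SE 1.45, 0.0446) and CXCL11 (5.99, SE 1.69, 0.043) of the interferon gamma list, TIGIT (3.90, 0.0403), ITGAE (2.93, 0.0275), NCR1, CD79A and MS4A1. CXCL10, which draws T cells, averaged 156 ± 127 CPM against 4.57 ± 3.02 CPM. CD8A averaged 63.0 ± 34.8 CPM in IND-PALF and 13.5 ± 17.5 CPM in CONTROL and was not called (2.24, SE 1.33, adjusted p = 0.371), nor was the T cell receptor subunit CD3E (1.94, adjusted p = 0.327). Adjusted over the list alone, 8 interferon gamma genes, 6 B cell genes, 4 resident memory genes, 2 NK genes, 1 checkpoint gene, 0 T cell genes, 0 CD8 genes and 0 Kupffer genes passed.

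Leaving out CONTROL replicate 1 ended the list calls of T cells (median 0.75), CD8 genes (1.18), resident memory (1.62), checkpoint genes (1.10), NK cells (1.15) and Kupffer cells (0.70), and kept those of B cells (2.90) and interferon gamma (1.17). Without CONTROL replicate 2 the same lists stayed called with larger medians: T cells 5.27, CD8 genes 6.45, resident memory 3.66, checkpoint genes 4.39, NK cells 4.81, Kupffer cells 3.26, B cells 3.27 and interferon gamma 3.48. CIITA (2.20 and 3.98 without replicates 1 and 2), CXCL10 (4.54 and 5.99), ITGAE (3.01 and 2.86), CXCL11, NCR1 and MS4A1 lost their calls without either control, and TIGIT without replicate 1 (2.84, adjusted p 0.339). MS4A1, a B cell surface gene, had 0 reads in both controls, so that IND-PALF was at least 21.73-fold higher against a floor of 3 counts over the controls. FCRL3, a receptor of B and T cells, had 2 control reads and an IND-PALF ratio of 83.0 (interval 23 to 684.9, edgeR adjusted p = 0.0051), and was not called without CONTROL replicate 1 (adjusted p 0.112). NCR1, an NK cell receptor, had 1 control read and a ratio of 35.8 (6.4 to 1415), and CD79A of B cells had 3 and a ratio of 18.4 (6.3 to 89.5). With MS4A1 at its floor the median of the B cell list stayed at 3.09.

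The remaining 11 lists were not called between IND-PALF and CONTROL with both controls. Their median log2 fold changes and camera adjusted p were 1.19 and 0.302 for plasma cells, −0.57 and 0.211 for monocyte-derived macrophages, 0.26 and 0.272 for the inflammasome and cytokines, 0.42 and 0.427 for stellate cells and matrix, 0.76 and 0.353 for cholangiocytes, 0.14 and 0.241 for sinusoidal endothelium, −0.44 and 0.301 for vascular endothelium, and 1.04 and 0.537 for erythroid genes. The type I interferon response had a median of −0.02 and a mean of 0.07 (adjusted p 0.797). Neutrophil markers had a median of 0.01 and a mean of −0.07 (0.675). Fetal liver genes had a median of 0.47 and a mean of 1.30, with camera pointing down (0.689). AFP, a fetal liver protein, averaged 92.7 ± 315 CPM over the 16 IND-PALF libraries, an SD above the mean (adjusted p = 0.358). Without CONTROL replicate 1 the macrophage list was called (−1.10), and without replicate 2 the inflammasome (1.64) and sinusoidal lists (1.35) were.

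The DX-PALF group against CONTROL is the same question for the other group of children. Few genes were called, 5 higher and 36 lower. EGLN3 (ENSG00000129521), an oxygen sensor that low oxygen induces, averaged 3.08 ± 1.86 CPM in DX-PALF (SD, n = 6) against 56.0 ± 13.3 CPM in the controls (n = 2), a log2 fold change of −4.41 (SE 0.51, edgeR adjusted p = 8.95e-05), below both controls in 6 of 6 libraries. LCN2 (ENSG00000148346), an iron-binding acute phase protein, averaged 7.78 ± 3.87 CPM against 138 ± 80.8 CPM, a log2 fold change of −4.33 (SE 0.53, adjusted p = 0.000133). With edgeR, 5 genes rose and 36 fell among 15542, all by at least 2-fold, and 1242 had an unadjusted p under 0.05. The 5 that rose were CDK1 (3.0, SE 0.65, adjusted p = 0.0416), E2F8 (3.60, 0.0379), FANCI (2.55, 0.0154), HELLS (2.46, 0.0333) and KIF22 (1.83, 0.0454). Among other falls were TMC5 (−4.74, SE 0.72, adjusted p = 0.00222), the matrix-linking enzyme LOXL4 (−4.15, 0.0416), the BMP antagonist GREM1 (−5.91, 0.0292), C2CD4A (−4.93, 0.00205), FGF23 (−4.23, 0.0416) and IL1B (−4.33, 0.0268).

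Calls in this comparison moved with single libraries. Without CONTROL replicate 1, 3 genes rose and 84 fell, and without CONTROL replicate 2, 0 rose and 18 fell with edgeR (855 genes at an unadjusted p under 0.05; with both controls, voom gave 0 higher and DESeq2 175). Leaving out DX-PALF replicates 1 to 6 in turn gave 5, 9, 57, 1, 4 and 1 higher genes and 32, 30, 52, 11, 14 and 9 lower ones. In the 4 low-share DX-PALF libraries against the controls, 2 genes rose and 11 fell, including 8 of the 41 calls. EGLN3 and TMC5 kept their calls in every alternative run, and LCN2 lost its call only with just the 2 groups fitted (adjusted p 0.062). Without CONTROL replicate 2, LOXL4 went to −0.27, IL1B to −0.20, C2CD4A to −1.94, FGF23 to −3.23 and GREM1 to −4.23, none called. All 5 higher genes lost their calls without either control, with log2 fold changes from 1.59 to 4.20. Leaving out DX-PALF replicates 4, 5 or 6, and for some genes 1 or 2, ended the calls of E2F8, HELLS, KIF22, FGF23, GREM1, IL1B and LOXL4, and leaving out 1, 4 or 6 that of CDK1, all with edgeR adjusted p from 0.0509 to 0.105 and log2 fold changes close to those with all libraries (CDK1 2.73 to 2.93, KIF22 1.58 to 1.93). The high-share libraries include no control, so they give no value for either comparison against CONTROL.

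Camera called 5 of 28 lists between DX-PALF and CONTROL, and none passed with an estimated correlation (lowest adjusted p 0.417) or by fry. Cell cycle genes had a median log2 fold change of 2.65 (camera adjusted p = 1.77e-13, 1 of 15 genes called, 13 adjusted over the list alone). Acute phase proteins had −1.66 (8.51e-06, 1 of 13 called, 4 adjusted over the list alone). B cell markers had 1.59 (0.00702, 0 of 9 called, 2 adjusted over the list alone), interferon gamma genes 0.56 (0.0391, 0 of 16 called) and monocyte-derived macrophage markers −0.49 (0.0276, 0 of 12 called, 1 adjusted over the list alone). Restricted to low-share libraries, these were 2.17, −1.44, 2.00, 0.22 and −1.02, and the interferon gamma list was not called (adjusted p 0.25). That list also lost its call without CONTROL replicate 1 (0.06) and without DX-PALF replicates 1, 5 or 6. The macrophage list lost its call without CONTROL replicate 2 (0.30) and without DX-PALF replicates 3 or 5.

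The other 23 lists were not called between DX-PALF and CONTROL with all libraries. Hepatocyte lists lay near 0: secreted proteins −0.07 (camera adjusted p 0.924), coagulation factors −0.36 (0.783), bile acid synthesis 0.07 (0.783), fatty acid oxidation 0.18 (0.313) and gluconeogenesis 0.23 (0.783). The urea cycle had a median of −0.09 and a mean of −0.13 with camera pointing up (0.783), and P450 genes a median of −0.10 and a mean of 0.08 (0.244). The immune medians were 0.40 for T cells (0.229), 1.07 for CD8 genes (0.109), 0.39 for resident memory (0.871), 0.73 for checkpoint genes (0.429), 1.17 for NK cells (0.0931), 1.03 for plasma cells (0.121), 0.18 for type I interferon (0.783), 0.25 for Kupffer cells (0.783), −1.47 for neutrophils (0.482) and −0.43 for the inflammasome and cytokines (0.429). The rest were −0.44 for stellate cells (0.153), −0.28 for cholangiocytes (0.0623), −0.44 for sinusoidal endothelium (0.192), −0.65 for vascular endothelium (0.0526), 1.20 for erythroid genes (0.0623) and −1.14 for fetal liver genes (0.265). ALB averaged 44750 ± 57190 CPM in DX-PALF, with a log2 fold change of 0.17 against CONTROL (edgeR adjusted p = 0.999).

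Several of these 23 lists hung on 1 control. Without CONTROL replicate 2, camera called T cells (3.95, adjusted p 1.25e-08), CD8 genes (5.75, 1.25e-08), checkpoint genes (2.87, 0.000319), NK cells (3.78, 0.00417), Kupffer cells (2.40, 0.000972), plasma cells (3.91, 0.00469) and erythroid genes (1.72, 0.00615) higher, and cholangiocytes (−0.42, 0.0353) and fetal liver genes (−1.52, 0.0338) lower. Without CONTROL replicate 1 it called T cells (−0.51, adjusted p 0.0153), Kupffer cells (−0.62, 0.0281), the inflammasome and cytokines (−1.11, 0.005), neutrophils (−2.28, 0.0187) and sinusoidal endothelium (−1.24, 0.00276) lower, and P450 (1.99, 0.00224) and fatty acid oxidation (1.10, 0.0116) higher. The type I interferon list reversed and was called lower in the low-share libraries (−0.54, adjusted p 8.01e-05) and with voom (−0.66, 0.0163). T cell, Kupffer and P450 medians changed sign with the control left out. Leaving out DX-PALF replicate 2 or 4 also called CD8 genes (1.12 and 1.44) and vascular endothelium (−0.60 and −0.52), replicate 2 NK (1.23) and plasma cells (1.07), replicate 4 erythroid genes (1.59) and stellate cells (−0.64), and replicate 3, 4 or 6 cholangiocytes (−0.49, −0.30 and −0.31).

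**Figure D2:**
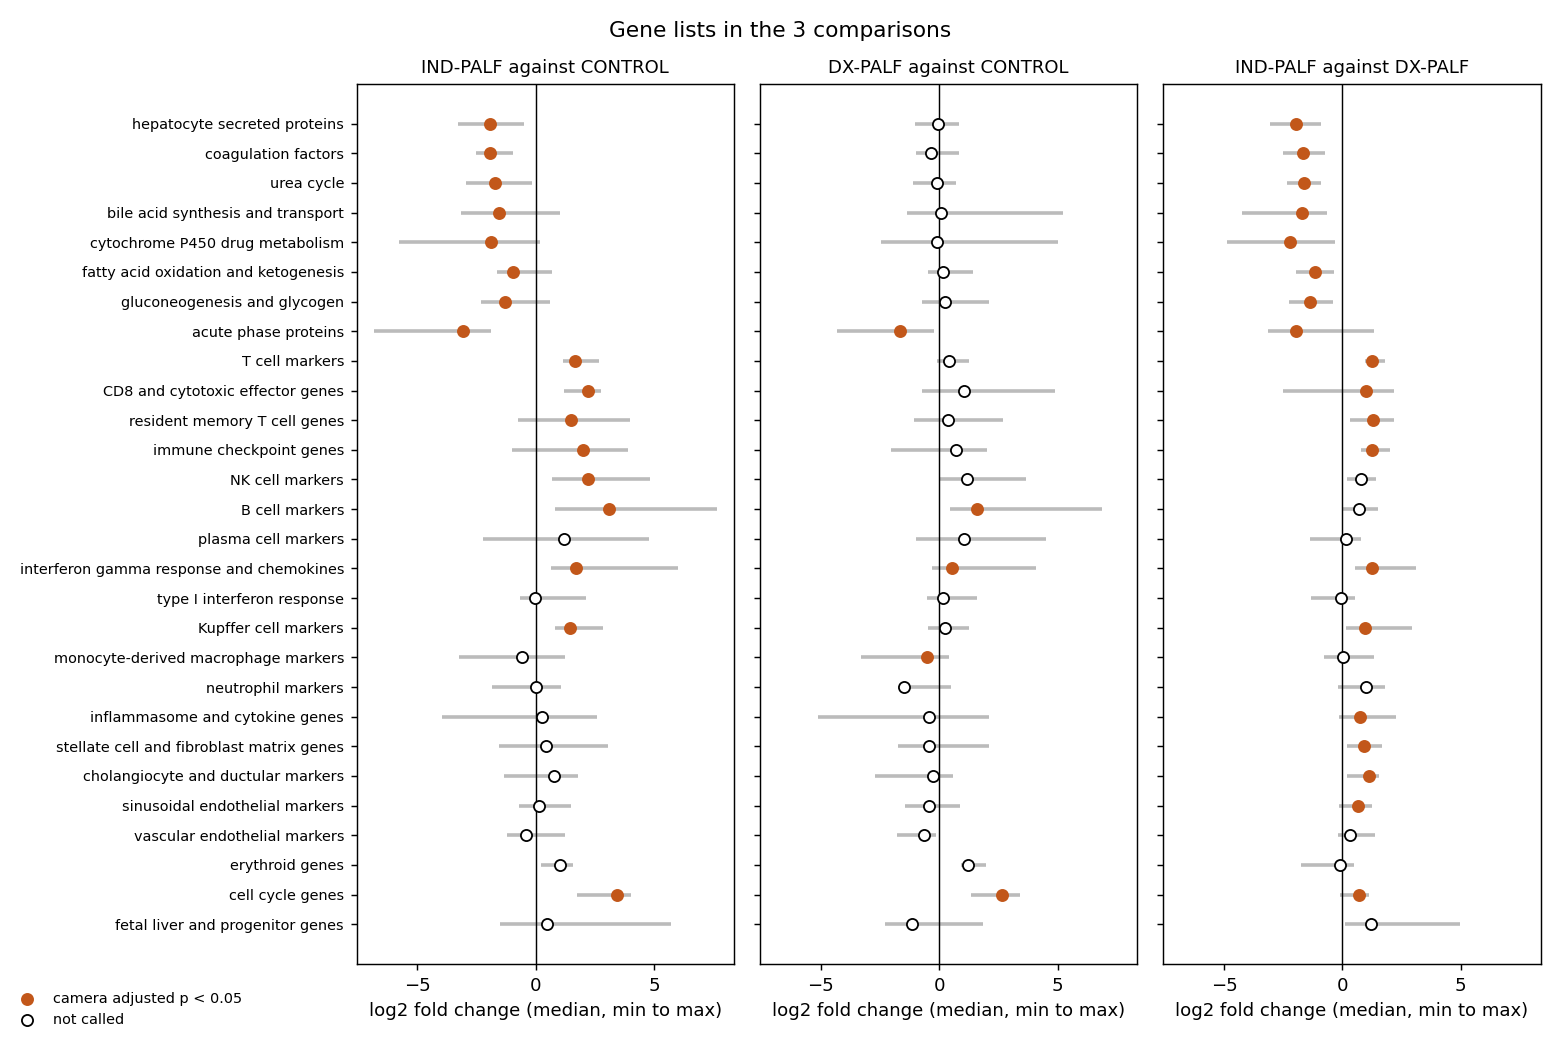
Median log2 fold change of each gene list (x axis) in the 3 comparisons (panels), with a grey bar from the lowest to the highest gene of the list, filled orange where camera's adjusted p is under 0.05 and open where it is not. Cell cycle genes lie at 3.43, 2.65 and 0.71 and acute phase proteins at −3.09, −1.66 and −1.95 for IND-PALF against CONTROL, DX-PALF against CONTROL and IND-PALF against DX-PALF.

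The comparison of IND-PALF with DX-PALF sets the 2 groups of children against each other, with the most libraries on both sides. By camera, lists of hepatocyte function were lower in IND-PALF and lists of T cell, resident memory and interferon gamma genes were higher, with few single genes called and none of these lists passing with an estimated correlation (lowest adjusted p = 0.311). CYP3A4 (ENSG00000160868) averaged 14.9 ± 35.4 CPM in IND-PALF (SD, n = 16) against 330 ± 361 CPM in DX-PALF (n = 6), a log2 fold change of −4.68 (SE 1.07, edgeR adjusted p = 0.0205). CXCR6 (ENSG00000172215), a homing receptor of T cells that stay in the liver, averaged 33.5 ± 16.8 against 7.68 ± 8.07 CPM, a log2 fold change of 2.07 (SE 0.53, adjusted p = 0.0339), above all DX-PALF libraries in 12 of 16. HLA-DOA (ENSG00000204252), which regulates peptide loading on MHC class II, averaged 93.2 ± 55.4 against 17.6 ± 14.5 CPM, a log2 fold change of 2.25 (SE 0.58, adjusted p = 0.0362). With edgeR, 71 genes rose and 348 fell among 15542, 55 and 301 of them by at least 2-fold, and 3391 had an unadjusted p under 0.05. In the low-share libraries (10 against 4), 898 rose and 887 fell, including 371 of the 415 calls that could be tested. All but 2 of these IND-PALF libraries lie in a different run of sample titles from the DX-PALF ones. In the high-share libraries (6 against 2), edgeR called 0 of 8454 genes, with 482 at an unadjusted p under 0.05, and no other tool was run there.

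Single DX-PALF libraries moved these counts in both directions. Without DX-PALF replicate 1, 818 genes rose and 942 fell, and without replicates 2 to 6 in turn 34, 2, 14, 2 and 67 rose and 266, 89, 232, 73 and 395 fell. Of the 24 genes named by rule and called here, CNDP1 and CYP2A7 kept their calls in every alternative run that tested them. The run on the high-share libraries alone did not test them and called 0 genes. The others each lost theirs in at least 1 alternative. Without DX-PALF replicate 5, AKR1D1 (−2.12, adjusted p 0.243), CYP7A1 (−2.56, 0.246), CYP1A2 (−3.21, 0.166), HAO2 (−3.07, 0.117), F11 (−1.83, 0.21), ACADS (−1.31, 0.147) and CYP3A4 (−4.14, 0.0844) lost their calls. Without replicate 3, NAGS (−2.28, 0.052) lost its call, as did CYP3A4 (−4.34, 0.0674), CYP7A1, F11 and ACADS, and F11 did without replicate 4 as well (−2.58, 0.0545). SAA2 lost its call without replicates 2, 3 or 4 (−1.90, −3.33 and −3.19). All higher genes named here lost their calls without replicate 3 and without replicate 5 (CXCR6 1.92 and 1.84, HLA-DOA 2.08 and 2.32, IDO1 2.87 and 3.52). Most did so without replicate 4 too, and some without replicate 2 or 6, with adjusted p of at most 0.16.

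Among the falls in IND-PALF against DX-PALF were CNDP1, a carnosine-cleaving enzyme (log2 fold change −5.47, SE 0.84, adjusted p = 0.00149), CYP1A2 (−4.88, adjusted p = 0.0143), CYP2A7 (−4.78, 0.00202), CYP3A4 and the peroxisomal oxidase HAO2 (−4.41, 0.00845). NAGS (−2.34, SE 0.51, adjusted p = 0.0143) was below all 6 DX-PALF libraries in 16 of 16. AKR1D1 (−4.12, 0.0131) and CYP7A1 (0.025), both of bile acid synthesis, the coagulation factor F11 (−2.53, 0.032), ACADS of fatty acid oxidation (−1.66, 0.0247) and SAA2 (−3.13, 0.0286) fell too. CYP7A1 had 10 reads over all IND-PALF libraries and 144 over DX-PALF. These genes kept their calls in the low-share libraries, with CYP3A4 at −7.23, except SAA2 (−1.85, adjusted p 0.146). HSPA6 (−6.67), HSPA1B (−5.34) and HSPA1A (−4.79), inducible heat shock chaperones, were also called, and DX-PALF replicate 2 alone carried them. That library had 1892 CPM of HSPA6, 2665 of HSPA1B and 3339 of HSPA1A, against at most 6.9, 61.2 and 85.2 CPM in the other 5 DX-PALF libraries, and without it HSPA6 had a log2 fold change of 0.43 and none of the 3 was called.

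Besides CXCR6 and HLA-DOA, genes that rose in IND-PALF against DX-PALF were IDO1 (3.12, SE 0.86, adjusted p = 0.0482), the enzyme that degrades tryptophan, and the receptor ADGRE1 (3.43, 0.0292). PLA2G2D (4.22, 0.0298), a secreted phospholipase, FCRL3 (2.37, 0.0255), ANKRD22 (2.58, 0.0474), LYPD6B (2.73, 0.0165) and TMC5 (2.21, adjusted p = 0.0332) rose too. CRTAM, a receptor of cytotoxic T cells, rose by 2.18 (adjusted p = 0.0483). All of these kept their calls in the low-share libraries, with log2 fold changes from 2.25 to 4.49. CD8A had 28.2 ± 52.1 CPM in DX-PALF and was not called (1.11, adjusted p = 0.407), nor were CD3E (1.02, 0.374), CXCL9 (2.39, 0.109), PDCD1 (1.79, 0.145) and ALB (−1.36, 0.41). Low-share libraries alone gave CD8A 2.89 (adjusted p 0.0386) and CD3E 2.34 (0.039), both called.

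All 7 hepatocyte lists were lower in IND-PALF than in DX-PALF by camera, and 0 of 28 lists passed with an estimated correlation (lowest adjusted p 0.311) or by fry. Median log2 fold changes were −1.96 for secreted proteins (adjusted p = 1.3e-09, 0 called, 8 adjusted over the list alone), −1.67 for coagulation factors (7.31e-09, 1 and 1), −1.64 for the urea cycle (3.04e-06, 1 and 4), −1.70 for bile acid synthesis (5.94e-09, 4 and 13), −2.20 for P450 (1.85e-12, 4 and 11), −1.17 for fatty acid oxidation (9.07e-08, 2 and 9) and −1.35 for gluconeogenesis (5.11e-06, 0 and 3). Acute phase proteins were at −1.95 (2.34e-06, with 2 called, and 8 lower and 1 higher adjusted over the list alone). Within the low-share set these 8 medians ran from −2.61 (P450) to −1.60 (fatty acid oxidation), all called by camera, and chance was not excluded for the number of lists called there. In the high-share libraries they were −1.09, −0.04, 0.62, 0.18, −0.65, 0.58, −0.26 and −1.29 in the same order, with only secreted proteins, coagulation factors, P450 and acute phase proteins called.

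Immune lists higher in IND-PALF than in DX-PALF by camera were T cells (median log2 fold change 1.24, adjusted p = 4.01e-07), CD8 genes (1.0, 4.75e-05), resident memory genes (1.28, 0.000378), checkpoint genes (1.24, 0.000378), interferon gamma genes (1.27, 6.2e-09), Kupffer cells (0.94, 3.17e-05) and the inflammasome and cytokines (0.75, 0.0084). Lists of other cells were higher as well: stellate cells and matrix (0.92, 0.00307), cholangiocytes (1.11, 0.000249), sinusoidal endothelium (0.64, 0.000944) and cell cycle genes (0.71, 2.15e-05). With an estimated correlation these 11 lists had adjusted p = 0.311 to 0.454. Adjusted over the list alone, 13 interferon gamma, 8 cholangiocyte, 4 resident memory, 2 CD8, 2 inflammasome, 1 checkpoint and 0 T cell, Kupffer, stellate, sinusoidal and cell cycle genes passed upwards. The immune medians were larger in the low-share libraries: T cells 2.52, CD8 genes 2.69, resident memory 2.14, checkpoint 2.06, interferon gamma 1.62, Kupffer 1.95 and inflammasome 1.14, all called. Leaving out DX-PALF replicate 1 alone gave much the same: T cells 2.47, CD8 genes 2.65, resident memory 2.13, checkpoint 2.03, interferon gamma 1.57, Kupffer 2.22 and inflammasome 1.07. In the high-share libraries they were −0.72, −0.85, 0.54, 0.05, 0.71, 0.09 and −0.38, none called. Stellate, cholangiocyte, sinusoidal and cell cycle lists had 0.73, 0.98, 0.59 and 0.82 in the low-share libraries, where the stellate and sinusoidal lists were not called, and 0.92, 1.61, 0.83 and 0.54 in the high-share ones, where the last was not called.

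The other 9 lists were not called between IND-PALF and DX-PALF: NK cells (0.79, camera adjusted p 0.118), B cells (0.69, 0.445), monocyte-derived macrophages (0.04, 0.276), neutrophils (0.99, 0.154), vascular endothelium (0.34, 0.276), erythroid genes (−0.08, 0.138), fetal liver genes (1.22, 0.32), plasma cells (median 0.14, mean −0.04, 0.549) and type I interferon (−0.05, 0.873). By camera the type I interferon list was higher in IND-PALF in the low-share libraries (0.70, adjusted p 0.0023) and lower in the high-share ones (−0.88, adjusted p 4.49e-05). Its score differed by 0.67 in the low-share libraries (exact permutation p 0.015, adjusted p 0.035). In the high-share ones, 6 against 2, it differed by −1.2 and did not pass (exact permutation p 0.107, adjusted p 0.714). NK cells (1.35), neutrophils (1.59) and monocyte-derived macrophages (0.99) were called higher in the low-share libraries. Neutrophils were called without DX-PALF replicate 1 (1.53) and erythroid genes without replicate 4 (−0.36).

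Scores per library set the lists against the spread between libraries, and 0 of 28 passed adjustment in an exact permutation test with all libraries (lowest adjusted p 0.183 for IND-PALF against CONTROL, 1.0 for DX-PALF against CONTROL and 0.0536 for IND-PALF against DX-PALF). Splits of 16 and 2 libraries allow no exact p under 0.00654, and splits of 6 and 2 none under 0.0357, so little could pass. The values against CONTROL therefore do not show that the lists lay within the spread between libraries. For IND-PALF against DX-PALF, 19 list scores passed without DX-PALF replicate 1 and 11 without replicate 6. Cell cycle scores were 4.27 ± 0.73 in IND-PALF (n = 16) against 1.47 ± 0.31 in CONTROL (n = 2), with an unadjusted exact p of 0.00654, the smallest that the splits of 16 and 2 libraries allow. Acute phase scores were 4.91 ± 2.19 against 9.82 ± 0.15 (exact p 0.0131). P450 scores were 3.13 ± 2.30 in IND-PALF (n = 16) against 6.46 ± 1.21 in DX-PALF (n = 6), with an exact p of 0.00347, and interferon gamma scores were higher by 1.89 (exact p 0.00513). T cell scores were 3.40 ± 1.28 against 1.43 ± 1.97 (exact p 0.0106). DX-PALF replicate 1, a high-share library, had a T cell score of 4.56 and a CD8 score of 4.84, above all but 1 and all 16 of IND-PALF. In the low-share libraries (10 against 4), 13 of 28 lists passed the exact permutation test: T cells were higher by 2.50 (adjusted p 0.00932, 10 of 10 above all 4), CD8 genes by 2.45 (0.0112), resident memory genes by 1.88 (0.00932) and interferon gamma genes by 2.12 (0.014), while P450 genes were at −3.91 (0.021). In the high-share libraries (6 against 2) 0 passed, and the T cell difference was 1.05 (exact p 0.714). The low-share groups also lie largely in different runs of sample titles, which the permutation test does not allow for.

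**Figure D3:**
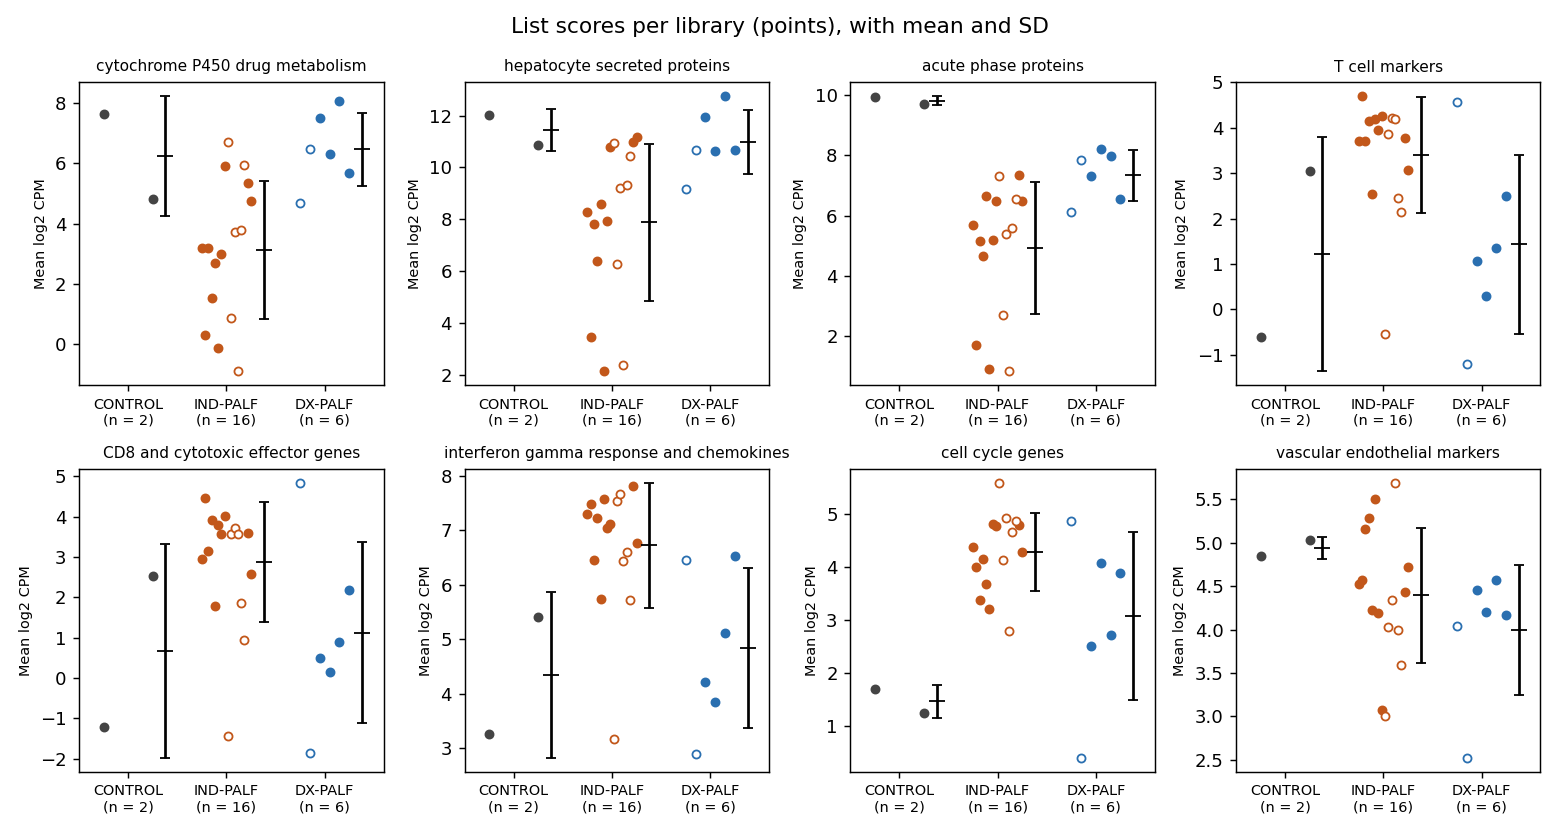
Scores per library (y axis, mean log2 CPM of a list's genes) by group (x axis), with open symbols for the 8 high-share libraries and CONTROL shown as 2 points. In the low-share libraries all 10 of IND-PALF lie above all 4 of DX-PALF in T cell score, and the high-share DX-PALF replicate 1 lies at 4.56.

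The spread of scores between libraries did not differ between IND-PALF and DX-PALF for any of 28 lists after adjustment (exact permutation test, lowest p 0.0319 for cell cycle genes, adjusted p 0.423, SD ratio 0.46). Across all 16 IND-PALF libraries the CD8 score had a gap of 0.404 of its range, over the limit of 0.4 set in advance, and across the 6 high-share ones a gap of 0.462, so no relation is given for either. Across the 10 low-share IND-PALF libraries, 3 of 27 relations passed. CD8 scores rose with T cell scores (r = 0.98, permutation p = 2e-05, adjusted p 0.00054, rho = 0.96, p = 4e-05), resident memory scores (r = 0.95, permutation p = 9e-05, adjusted p 0.0012, rho = 0.93, p = 0.00041) and checkpoint scores (r = 0.90, permutation p = 0.00063, adjusted p 0.0057, rho = 0.83, p = 0.0047). Without the 2 libraries farthest from the median CD8 score, r was 0.94, 0.85 and 0.62. The relation with secreted hepatocyte proteins was not called (r = −0.44, permutation p = 0.2, adjusted p 0.44).

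Both comparisons with CONTROL called 5 genes higher and 32 lower in common, with 0 in opposite directions. Independent lists of these sizes would share 0.08 and 0.96 genes, and 20 simulated data sets of unchanged groups against the same controls shared at most 1 higher and 0 lower. Leaving out CONTROL replicate 1 gave 3 and 68 shared genes, leaving out CONTROL replicate 2 gave 0 and 17 (each with edgeR), and leaving out DX-PALF replicate 3 gave 55 higher. The log2 fold changes of the 2 comparisons had a correlation of 0.70 across genes, which are not independent replicates, against a median of 0.81 in the simulated sets. Their covariance was 0.612 against 0.347 (0.324 to 0.375), and 74.1% of genes had the same sign against 78.8%. The 2 controls cannot be split so that each part keeps 2 libraries, so part of the excess can come from the shared controls.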

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

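Some tests were chosen only after the results were seen. They were those within the low-share and high-share libraries, the removals of libraries, and the tests of single explanations given here. Most of their predictions were written down before each was run. Exceptions were the test in the same range of share, the parting of random removals by DX-PALF replicate 1 and the splits for low-share lists. Their values were part of results seen before. No bound was written for T cell minus erythroid, neutrophil, stellate or sinusoidal scores, or for T cell minus hepatocyte scores in the high-share libraries.

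For DX-PALF, the only group of 4 to 10 libraries, the sizes screened here, 110 measures were screened for a library whose gap to the nearest of the other 5, divided by the group's range, passed Dixon's limit. Chance passes about 1 in 20 groups. Of the measures, 9 passed: 0 of 4 library measures, 1 of 28 list scores and 8 of 78 named genes. DX-PALF replicate 2, the shallowest library, gave 8 of them. Its vascular endothelial score of 2.52 lay below the next lowest of 4.04 (gap share 0.741). It had no reads of ASPM (0.696), CDK1 (0.655), CYP7B1 (0.784) and HLA-DOA (0.691), at a log2 CPM of −1.86 against 1.95 to 4.19 in the next lowest library. It was highest in HSPA1A (0.701), HSPA1B (0.679) and HSPA6 (0.705), with log2 CPM of 11.71, 11.38 and 10.89 against 6.42, 5.94 and 2.84 in the next highest. DX-PALF replicate 5 was lowest in LCN2 (0.702), at 0.54 against 2.73. At 587080 counts, 1 read in DX-PALF replicate 2 weighs much, so the 4 genes without reads may follow from depth; the 3 chaperones are not low counts, and HSPA6 had a log2 fold change of 0.43 between IND-PALF and DX-PALF without that library.

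The first pattern weighed is that more genes separated IND-PALF from DX-PALF in the 16 low-share libraries (1785) than in all 24 (419). Removing 6 IND-PALF and 2 DX-PALF libraries at random gave at least 1785 calls in 5 of 100 draws (median 24, highest 2407). That is the number set in advance for a smaller set as the cause, but this bound did not part set size from DX-PALF replicate 1, which all 5 draws took out. The 63 draws of the same size that kept it had a median of 7 calls, at most 437, against a median of 319 in the 37 that took it out. These values argue against a smaller set alone. DX-PALF replicate 1 is a candidate explanation: leaving out the other 7 high-share libraries and keeping it gave 121 calls, and leaving it out of all 24 gave 818 higher and 942 lower genes. Its T cell score was the highest of its group at 4.56, and whether that is the tissue or the label was not tested. Of 100 splits of the 14 low-share IND-PALF and DX-PALF libraries into 10 and 4, 1, the real one, gave as many calls (1785). The highest other gave 1262, and the rest at most 4. These values argue against chance, but 100 splits cannot exclude it. The low-share set was chosen after seeing the counts and leaves out DX-PALF replicate 1, which the splits do not allow for. In this set all but 2 IND-PALF libraries also lie in a different run of sample titles from DX-PALF. The splits cannot part the group from that run.

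The second pattern is that hepatocyte lists were lower and T cell and interferon gamma lists higher in IND-PALF than in DX-PALF. Of 100 splits of the 22 IND-PALF and DX-PALF libraries, 1, the real one, gave as many called genes (419, highest other 37). This argues against chance for the genes. For the lists chance stays open: 11 of 100 splits gave at least 19 called lists (highest other 25). Nearly all of the other splits called at least 1 list. In the low-share libraries 6 of 100 gave at least 21 (highest other 24). Fewer hepatocytes would raise the markers of every other cell type alike. The T cell score minus the vascular endothelial score was higher in IND-PALF by 1.57 (exact permutation p = 0.0162), which argues against that as the whole cause. The T cell score minus the erythroid score (2.44, exact p 0.000134) and minus the neutrophil score (1.12, exact p 0.0396) was higher too. Both lists are of blood cells, and their mean scores were low (1.05 and 2.34 in IND-PALF, 1.52 and 1.49 in DX-PALF). Without a bound or adjustment, these 2 contrasts do not decide. T cell minus stellate (1.02, exact p 0.201) and minus sinusoidal scores (0.76, exact p 0.186) did not pass. Scores of Kupffer cells (2.21) and cholangiocytes (1.27) were higher in IND-PALF as well, beside 1.97 for T cells. Fewer hepatocytes can therefore remain part of the cause. The share of counts in the 2 unnamed IDs stood for library quality. As the whole cause, this share is argued against by the T cell minus hepatocyte score. Within the low-share libraries that score was higher in IND-PALF by 6.24 (exact permutation p = 0.00599). Both lists had already been seen to differ, and this set leaves out DX-PALF replicate 1. Shares in these libraries still ran higher in IND-PALF, up to 24.8% against 7.2%. Between the 5 IND-PALF and 4 DX-PALF libraries with shares of at most 7.2%, the difference was 5.92 (exact permutation p = 0.0317), with T cell scores higher by 2.43 (exact p 0.00794) and the hepatocyte score alone not past the threshold (−3.49, exact p 0.0873). In the 8 high-share libraries the difference was 2.88 (exact p 0.5), with 4 of 6 above the DX-PALF mean, too few libraries to decide. Only IND-PALF replicates 15 and 16 lie in the same run of sample titles as the low-share DX-PALF libraries. Their T cell scores (3.77 and 3.08) lay above the range of those libraries (0.30 to 2.50). Their secreted protein scores (10.98 and 11.19) lay within it (10.64 to 12.75), and their P450 scores (5.35 and 4.75) below it (5.69 to 8.06). So few libraries cannot part the group from the run of titles. A real difference in immune infiltrate or in hepatocyte function between the groups may remain, as may unknown differences between the children, such as the time of sampling, which the labels do not give.

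The third pattern is the set of genes lower in both PALF groups than in CONTROL. The shared controls remain a possible cause. Of such genes 32 were found, against at most 0 in 20 simulated sets without any change, but those sets had a higher correlation of the 2 comparisons (0.81 against 0.70) and more genes of the same sign (78.8% against 74.1%). The covariance lay above the simulated range (0.612 against 0.324 to 0.375). These measures go both ways, and each is set against a simulated spread of 2 controls, so the bound set in advance on the count does not decide, and the controls cannot be told apart from a change common to both groups. Low oxygen in the control tissue before freezing could raise genes in both controls: a score of hypoxia-inducible genes was lower in 22 of 22 PALF libraries (median 4.96, 4.36 to 5.50) than in the controls (6.28 and 5.79, exact permutation p = 0.00362). A loss of such expression in failing liver would look the same, so the 2 cannot be told apart with controls that have no record of handling. EGLN3, called in DX-PALF and itself induced by low oxygen, belongs to this pattern. The acute phase score lay below both controls in 16 of 16 IND-PALF and 6 of 6 DX-PALF libraries. CONTROL replicates 1 and 2 had 2010 and 1170 CPM of SAA1 and 1400 and 5850 CPM of CRP. A raised level of acute phase genes in these 2 controls cannot be told apart from a fall in both PALF groups.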

How the results depend on the processing

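The low-share set, the high-share set, the share as batch term, removal of the 2 IDs, and for scores the libraries left out in turn were chosen after seeing the counts. No paired analysis was possible because replicate numbers pair no samples. Where a value changed, the cause was not tested unless the setting itself removes libraries.

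Counts of called genes are given as higher/lower. Against CONTROL, IND-PALF (247/414) gave 176/274 with the total count as covariate, 87/292 with voom, 775/381 with DESeq2 and 523/570 in the low-share set. Other settings stayed within 1.5 times, and leaving out libraries in turn gave 14 to 327 higher and 1.5e+02 (rounded) to 533 lower. DX-PALF (5/36) gave 0/5 with only the 2 groups fitted, 3/33 with the covariate, 1/14 without the shallow libraries, 0/13 with voom, 175/79 with DESeq2, 2/11 in the low-share set and 2/26 with the batch term. Unadjusted p under 0.05 held for 800 genes with the 2 groups and for 1061 with voom. Leaving out libraries gave 0 to 57 higher and 9 to 84 lower. IND-PALF against DX-PALF (71/348) gave 33/166 with the covariate, 25/96 without the shallow libraries, 1222/1518 with voom, 433/653 with DESeq2, 898/887 in the low-share set and 0/0 in the high-share set (edgeR, 482 at an unadjusted p under 0.05). Leaving out libraries gave 2 to 818 higher and 73 to 942 lower.

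Lists called were 17, 5 and 19 of 28 for IND-PALF against CONTROL, DX-PALF against CONTROL and IND-PALF against DX-PALF. Camera with an estimated correlation called 0, 0 and 0 (lowest adjusted p 0.092, 0.417 and 0.311), and fry 2, 0 and 0, the 2 being acute phase proteins and cell cycle genes. Leaving out libraries gave 8 to 19 for the first and 3 to 13 for the second. The second also gave 11 with the 2 groups, 9 without the shallow libraries and 10 with voom, and the third gave 8 in the high-share set. Genes shared by both comparisons with CONTROL (5 higher, 32 lower) were 2 and 10 in the low-share set and 0 to 55 and 9 to 68 with libraries left out. List scores that differed between IND-PALF and DX-PALF (0) were 13 in the low-share set and 0 to 19 with libraries left out (19 without DX-PALF replicate 1 and 11 without DX-PALF replicate 6).

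Some directions reversed, with a call before or after the change. Without CONTROL replicate 1, CYP3A4 in IND-PALF against CONTROL went to 0.27 (range with libraries left out −6.40 to 0.27), and in DX-PALF against CONTROL T cells went to −0.51 (−0.66 to 3.95), interferon gamma to 0.06 with its camera direction turned (to 1.98), Kupffer cells to −0.62 (−0.83 to 2.40) and P450 to 1.99 (from −0.80). Without CONTROL replicate 2, IL1B in IND-PALF went to 1.08 (−4.02 to 1.08) and the macrophage list in DX-PALF to 0.30 (−1.11 to 0.30). The type I interferon list in DX-PALF against CONTROL was −0.66 with voom and −0.54 in the low-share set, called in both (adjusted p 0.0163 and 8.01e-05). In IND-PALF against DX-PALF it was 0.39 and 0.70, and HSPA6 was 0.53 without the shallow libraries, 0.62 with voom, 0.43 without DX-PALF replicate 2 (range −7.09 to 0.43) and 1.08 in the low-share set. In the high-share set the medians of the urea cycle (0.62), bile acid (0.18) and fatty acid oxidation lists (0.58) reversed. Those of the T cell (−0.72), CD8 (−0.85) and inflammasome lists (−0.38) did too, and none of these lists was called there. Differences in their scores kept the direction of all libraries: −1.29, −0.85, −0.04, 1.05, 0.55 and 0.51 in the same order. None of these score differences passed.

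Kept under every alternative run that tested them were the calls of 4 of 31 named genes for IND-PALF against CONTROL (CDK1, FGF23, SAA1, SAA2), 2 of 13 for DX-PALF against CONTROL (EGLN3, TMC5), 2 of 24 for IND-PALF against DX-PALF (CNDP1, CYP2A7) and no list. CNDP1 and CYP2A7 were not tested in the high-share set, where edgeR called 0 genes. Of 952, 699 and 890 values of named genes under alternatives, 866, 604 and 756 kept direction and side of the threshold. Spread ratios kept theirs in all 252 values. Relations across IND-PALF libraries gave no value under the alternatives, because the gap in CD8 scores barred the pooled relation. Depth limits the 8 high-share libraries most, where 8454 genes could be tested.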

Other observations

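Tests on 6 further gene lists (pericentral and periportal hepatocyte genes, MHC class II, complement, hypoxia-inducible genes and heat shock chaperones) were all chosen after the main results were seen; each prediction was written before its list was scored.

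MHC class II genes were predicted to be higher in IND-PALF than in DX-PALF. Their score was 7.77 ± 1.20 (n = 16) against 5.43 ± 2.6 (n = 6), higher by 2.34 (exact permutation p = 0.00788, adjusted over the 6 lists 0.0317), and higher by 2.08 in the low-share libraries (exact permutation p = 0.002). Complement genes, which hepatocytes secrete, were predicted to be lower and were at 6.59 ± 1.61 against 8.43 ± 1.26, a difference of −1.84 (exact permutation p = 0.0204, adjusted 0.0407), and −2.41 in the low-share libraries (exact permutation p = 0.02). Both values went the way predicted, on the same libraries as the main results. Hepatocyte lists had already been seen lower there, and the interferon gamma list, which holds HLA-DRA and HLA-DPA1, higher. The 2 scores are therefore no independent test of the hypotheses.

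Pericentral hepatocyte genes were predicted to be lower relative to periportal ones in IND-PALF. The difference between the 2 scores went the other way, −0.95 in IND-PALF against −2.71 in DX-PALF (exact permutation p = 0.00725), so the values argue against the hypothesis. The low-share libraries gave a difference of 1.52 (exact permutation p = 0.0699). Both scores were lower in IND-PALF, with differences of −3.22 for periportal genes (adjusted p 0.0317) and −1.46 for pericentral genes (0.0491). Heat shock chaperones other than HSPA1A, HSPA1B and HSPA6 differed by −0.57 (exact permutation p = 0.0638), and by −0.21 in the low-share libraries (exact permutation p = 0.142), where DX-PALF replicate 2 is absent and the SD of DX-PALF was 0.27 instead of 1.23. This leaves a broader heat shock response undecided. Hypoxia-inducible genes differed by −0.24 between IND-PALF and DX-PALF (exact permutation p = 0.0514, adjusted 0.0617), by −1.13 between IND-PALF and CONTROL (0.00654, adjusted 0.0392, lower in 16 of 16) and by −0.89 between DX-PALF and CONTROL (0.0357, adjusted 0.214). Against CONTROL, the other 5 lists did not pass for IND-PALF (adjusted p from 0.0784 to 0.902).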
